A study of Mus musculus with 12 samples.

How the data were processed

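Gene expression was measured in peritoneal macrophages of C57BL/6 mice on 12 one-colour Agilent mouse arrays, with 4 arrays in each of 3 groups: control, LPS plus IFNγ (LPS_IFNg), and LPS plus IFNγ plus emodin (LPS_IFNg_emodin). Per the labels' protocols, cells that had not attached were removed by washing 2 hours into culture, those left spent a night without serum, and Cy3-labelled cRNA was made from 200 ng of RNA. The series design text calls the 4 samples of a group biological replicates. The tissue label names peritoneal macrophages and the design text names another leukocyte, so marker genes of both were measured. Nothing links a sample to one animal, so p-values measure the spread between these samples.

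The deposited scanner files hold intensity values per spot, extracted with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. The processed signal used here is a background-subtracted intensity that was not normalised between arrays, per the file headers, and the flags for background, saturation and outlier spots are those of the same software. The deposited value table holds log2 values, which matched the quantile-normalised log2 processed signal after centring of each probe on its median over the 12 arrays. Its direction therefore follows signal, and its columns have medians between -0.0316 and 0.0416. Its columns for control replicates 1, 3 and 4 matched the scanner files of control replicates 4, 1 and 3, which leaves group means as they are. That table was used only as an alternative.

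Each of the 62976 spots of an array was read, 59305 of them not controls, and spots with an outlier flag were left out (78 to 415 per array). Spots of a probe were averaged, and the log2 processed signal had the 75th percentile of its array subtracted. A probe was kept when it was well above background on all 4 arrays of at least 1 group, which left 27380 of 55681 probes. Probes were named by matching their accessions, without versions, to a RefSeq table of assembly GRCm38.p6 that was used only for names, because the array design is annotated on mm9. This named 27509 probes with 20887 symbols, gave none several symbols and left 28172 unnamed. Of the kept probes 17168 had a symbol, and the probe with the highest mean over the 12 arrays stood for each of 13169 genes. For 3355 of these genes several probes were kept, and disagreements between probes are given for Iigp1, Pgm5, Gapdh, Irf1 and Cdkn1a, not for every gene.

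Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays, with 3 group means and 1 spread per gene (lmFit, contrasts and eBayes, 9 residual and 2.49 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and all adjusted p-values of single genes below are limma's. The 3 contrasts were LPS_IFNg against control, LPS_IFNg_emodin against LPS_IFNg, and LPS_IFNg_emodin against control. Errors of log2 changes are standard errors of that fit with 4 arrays per group. Where a probe was not well above background on any array of the dimmer group, the difference is a bound, given as "at least": the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal well above background. No depth exists for arrays, and the number of arrays limits the precision.

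Before the data were examined, 30 gene lists were fixed, 21 by function and 9 by cell type, holding 519 different genes of which 13 had no matching symbol. The 28 lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and limma's fry were alternatives, and no list passed with an estimated correlation in any of the 3 comparisons. Genes named below were chosen by a rule fixed before the data were examined: the largest rises and falls without overlap between groups, a set of activation, xenobiotic, housekeeping and sex-linked genes whatever their values, up to 4 members with the largest change per list, and the largest changes that emodin opposed or added to. Il12b belonged to the set but had no matching symbol, and Cyp1a1 and Ddx3y belonged to it but were not tested, since they were not well above background on all arrays of any group.

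The share of the LPS_IFNg change removed with emodin was estimated as minus the least-squares slope through 0, over genes called at 2-fold or more. The LPS_IFNg arrays were split into 2 and 2, so that the arrays choosing the genes differed from those measuring the reversal, and the mean over 6 splits is given. Because the LPS_IFNg arrays enter both contrasts, calls in both contrasts and their covariance were also computed in 50 simulations without an emodin effect and with these splits. Data simulated from the 13169 genes with 200 changed genes were used to test the code over 10 draws. For LPS_IFNg against control, 60%, 87% and 97.6% of changes of 1.5-, 2- and 4-fold were recovered, for LPS_IFNg_emodin against LPS_IFNg 62.4%, 89.9% and 98.3%, and for LPS_IFNg_emodin against control 63.4%, 90.1% and 97.4%. False calls made up 5.4%, 5.17% and 4.68% of the calls. These draws left out the scaling step and changed 200 genes, while 9086 to 10268 genes were called in the data. Their rates of recovery and of false calls need not hold for the real comparisons. In separate simulations for LPS_IFNg against control, with 1 list shifted and no other gene, a list shifted 2-fold was called in 10 of 10 draws. The noise of each gene was drawn independently, so these draws do not test the list calls for genes that vary together. The share removed was tested on 3 further draws, in which every gene had its measured LPS_IFNg change, and a true share of 0.3 was estimated as 0.294.

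All controls were on one slide and all treated arrays on another, scanned separately, so slide, scan and the age of the mice (8 against 9 weeks) cannot be told apart from treatment in both comparisons with control. The arrays of LPS_IFNg_emodin and LPS_IFNg shared a slide, the first in row 1 and the second in row 2, so row and emodin cannot be told apart either. Replicate numbers were taken to pair the arrays of these 2 groups. Deviations from the group means correlated at 0.229, 0.283, 0.162 and 0.151 across genes for the 4 shared numbers. The replicate number of each of these arrays is also its column on the slide, so these correlations cannot tell paired samples from a shared column. Sex-linked signals, given below, set replicate 3 of both groups apart, which a shared column would not produce. They cover that replicate number only. Alternatives were another background correction (normexp with an offset of 50, on median spot signals because the files hold no mean signal), quantile scaling, a percentile over detected probes, the value table, 2 other filters, the mean of a gene's probes, another prior, a replicate block, sex, fits on 8 arrays, and each array left out in turn. Scaling to 8 of the 10 spike-in sequences, a block on 8 arrays and leaving out replicate 3 of both treated groups were chosen after seeing the data. Statistics were computed in R, extraction and figures in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probes without a symbol were left out of the comparisons.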

Results

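Macrophages were compared after 20 hours in 3 conditions. Lipopolysaccharide (LPS, a bacterial cell wall component, 100 ng/ml) and interferon gamma (IFNγ, 20 ng/ml) were used together to induce classical activation, an inflammatory state of macrophages, and emodin, an anthraquinone from plants, was added at 50 μM in one group. The series title frames the question as whether emodin inhibits this activation. Each group had 4 arrays. The 75th percentile of the processed signal lay between 747 and 971 on control arrays, between 763 and 942 on LPS_IFNg arrays and between 435 and 548 on LPS_IFNg_emodin arrays, and between 46.3% and 51.8% of probes were well above background.

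The lower signal of the emodin arrays was not shared by the spike-ins, which are RNAs added in a fixed mix before labelling. Their mean log2 signal changed by -0.05 ± 0.06 (SE, n = 4 per group) between LPS_IFNg_emodin and LPS_IFNg, with an exact two-sided permutation p of 0.457, while the median gene changed by -0.89 ± 0.10, with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give. Within the 4 pairs of arrays with the same replicate number these exact p-values were 0.25 and 0.125, and 4 pairs cannot give less than 0.125. Log2 changes below are therefore relative to each array's own gene signal, and scaling to the spike-ins is named where it turns a direction or ends a call in LPS_IFNg_emodin against LPS_IFNg. It was not applied to the comparisons with control, because the spike-ins themselves differed by 2.45 between the slides.

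**Figure D1:**
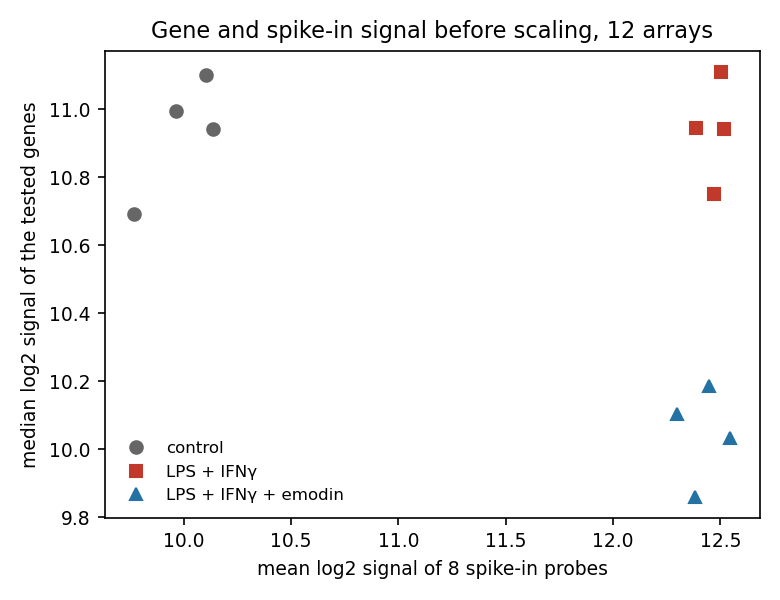
Median log2 signal of the 13169 tested genes against the mean log2 signal of 8 spike-in probes before scaling, with 1 point per array and 4 arrays per group. The emodin arrays lie at gene signals of 9.86 to 10.19 and the LPS_IFNg arrays at 10.75 to 11.11, at spike-in signals that overlap, and the control arrays, on the other slide, have spike-in signals of 9.77 to 10.14.

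With LPS plus IFNγ, known markers of classical activation rose by large factors. Nos2, the inducible nitric oxide synthase, rose by 11.54 ± 0.17 on the log2 scale (adjusted p = 3.93e-13), a 2973-fold difference. Cxcl9, a chemokine induced by IFNγ, was not well above background on any control array and was at least 10080-fold higher (adjusted p = 1.03e-12). The prostaglandin synthase Ptgs2 was at least 3049-fold higher and the cytokine Il6 at least 996-fold higher. Tnf rose by 6.27 ± 0.11, Il1b by 8.58 ± 0.43 and the costimulatory molecules Cd86 and Cd40 by 4.13 ± 0.22 and 7.39 ± 0.12.

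Of the 13169 genes tested, 9086 were called, 4487 up and 4599 down, and 3465 of them changed at least 2-fold. The balance depended on the processing, with 3795 up and 5577 down with the percentile over detected probes and 7899 up and 4746 down with no filter on dim probes. The 4 arrays of the groups did not overlap for 64.43% of genes, where chance gives 2.86%. Of the 20 tested classical activation markers, 19 rose and 1 fell, with a camera adjusted p of 8.49e-12 and adjusted p = 0.0732 with an estimated correlation. All 25 NF-kB target genes rose, with camera adjusted p = 4.82e-13 and adjusted p = 0.0725 with an estimated correlation, among them the chemokines Ccl2 (6.67 ± 0.32) and Cxcl2 (5.12 ± 0.20). All 27 interferon-stimulated antiviral genes rose, including Ifit2 (8.35 ± 0.24) and Ifit1 (6.58 ± 0.21), with camera adjusted p = 1.29e-15 and adjusted p = 0.12 with an estimated correlation. All 19 IFNγ-inducible GTPases and regulators rose, with Gbp5 at 9.66 ± 0.13 and Gbp4 at least 1279-fold higher, at camera adjusted p = 4.13e-15 and adjusted p = 0.0725 with an estimated correlation. Iigp1, of the same list, rose by 7.31 with the probe used and by 11.60 with its other probe.

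Antigen presentation rose with these lists. Of 16 genes of MHC class I presentation 15 rose, led by the peptide transporter Tap1 (4.62 ± 0.10), with camera adjusted p = 8.59e-08 and adjusted p = 0.0603 with an estimated correlation. All 11 genes of MHC class II presentation rose, with H2-Ab1 at 3.55 ± 0.19 and the class II transactivator Ciita at 4.06 ± 0.17, at camera adjusted p = 1.57e-05 and adjusted p = 0.15 with an estimated correlation. All 21 genes of glycolysis and hypoxia rose, such as Hk2, which phosphorylates glucose (3.26 ± 0.09), and the lactate transporter Slc16a3 (3.65 ± 0.09), with camera adjusted p = 2.32e-10 and adjusted p = 0.1 with an estimated correlation. Of 11 heat shock genes 7 rose and none fell, with Hspa1a at 6.00 ± 0.21, camera adjusted p = 0.00826 and adjusted p = 0.1 with an estimated correlation. Of 21 NRF2 targets, genes of the antioxidant response, 14 rose and 3 fell, with Slc7a11 at 4.12 ± 0.14, camera adjusted p = 0.0135 and adjusted p = 0.423 with an estimated correlation.

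Cholesterol synthesis fell. Of its 23 tested genes 22 fell, including Dhcr7 by -3.18 ± 0.15 and Idi1 by -2.87 ± 0.09, with camera adjusted p = 2.32e-10 and adjusted p = 0.1 with an estimated correlation. Of 13 LXR targets and lipid efflux genes 10 fell, among them Fasn by -1.76 ± 0.22, and 1 rose, the cholesterol exporter Abca1 by 0.68 ± 0.18, at camera adjusted p = 0.00746 and adjusted p = 0.0732 with an estimated correlation. Of 15 alternative activation markers, genes of the state induced by IL-4, 7 rose and 4 fell, and the list did not pass (camera adjusted p = 0.421). Its mannose receptor Mrc1 fell by -2.93 ± 0.28 and the lectin Clec10a by -4.41 ± 0.21. Among single genes, Mamdc2 fell by -7.60 ± 0.20, and Rgs18 and Cmbl, not well above background on any LPS_IFNg array, were at least 56.1-fold and at least 120-fold lower.

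For the counts of members called in this comparison, those adjusted over the list alone were equal to the counts above in every list named. The aryl hydrocarbon receptor list, with 6 of 8 genes up and 1 down, had camera adjusted p = 0.0489 and adjusted p = 0.223 with an estimated correlation. Among single arrays left out, its call ended without LPS_IFNg replicate 3 (0.0521) or 4 (0.0581), LPS_IFNg_emodin replicate 3 (0.0508) or 4 (0.0507), or control replicate 1 (0.0523) or 2 (0.0504). The number of lists called up also fell from 11 to 10 in other settings, among them the replicate block, the fit on 8 arrays and the mean of a gene's probes. Quantile scaling, a percentile over detected probes and the value table moved the median of all genes to -0.13, -0.16 and -0.13 here, from -0.03.

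With emodin added, the classical activation markers fell below their level with LPS plus IFNγ alone. Of the 20 markers 18 fell and none rose, with camera adjusted p = 3.4e-05 and adjusted p = 0.551 with an estimated correlation. The formyl peptide receptor Fpr2 changed by -5.09 ± 0.19 on the log2 scale (adjusted p = 1.57e-09), Il1b by -3.76 ± 0.43 (8.2e-06), the chemokine Cxcl10 by -3.11 ± 0.27 (7.3e-07) and Cd86 by -2.95 ± 0.22 (2.28e-07). Falls were smaller for Ptgs2 (-1.81 ± 0.28), Il6 (-1.63 ± 0.40), Nos2 (-1.47 ± 0.17) and Tnf (-0.65 ± 0.11). On the 4 emodin arrays, in order of replicate number, this list lay 5.80, 5.08, 5.22 and 5.30 above the control mean, and the mesothelial and fibroblast markers lay -1.33, -3.21, -2.97 and -2.07 from it. Cxcl9 and Cd40 had log2 differences of -0.00 ± 0.26 and -0.15 ± 0.12 and did not pass, though both passed with quantile scaling (-0.44 and -0.41) and with spike-in scaling (-0.73 and -0.87).

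**Figure D2:**
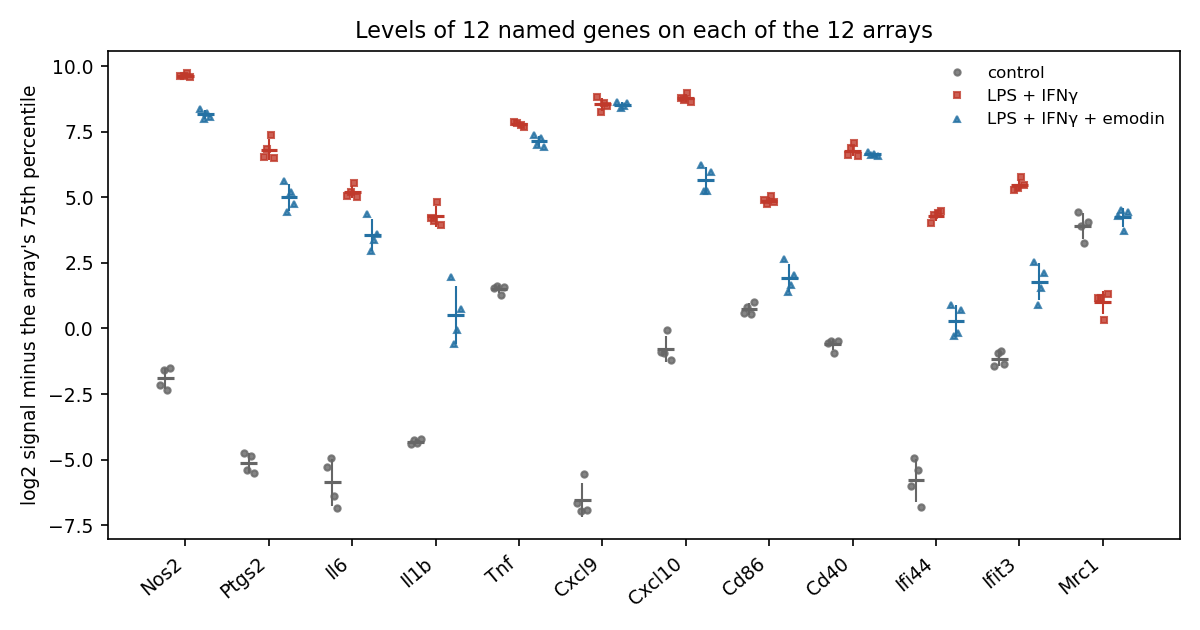
Log2 signal minus the array's 75th percentile for 12 named genes, with 1 point per array, and the mean and SD of the 4 arrays of each group as horizontal and vertical lines. Nos2 lay at -1.90 in control, 9.64 in LPS_IFNg and 8.16 in LPS_IFNg_emodin, and Mrc1 at 3.92, 0.99 and 4.24.

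The contrast of LPS_IFNg_emodin with LPS_IFNg called 9482 of 13169 genes, 4747 up and 4735 down, and 3499 changed at least 2-fold. With scaling to the spike-ins, an alternative chosen after seeing the data, 9937 were called, 1131 up and 8806 down, with a median change of -0.71. The arrays did not overlap for 67.54% of genes, where chance gives 2.86%. Without replicate 3 of both groups, whose sex-linked signals go against their labels, 8849 genes were called.

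Interferon-stimulated antiviral genes fell with emodin, 25 of 27, and none rose. The list lay 3.59, 2.82, 2.98 and 3.27 above the control mean on the 4 emodin arrays, the same order as the mesothelial and fibroblast markers. On the LPS_IFNg arrays the orders differed, with this list highest on replicate 3 and those markers on replicate 1. Ifi44 changed by -4.01 ± 0.38, Ifit3 by -3.69 ± 0.29 and the ISG15 protease Usp18 by -2.79 ± 0.22, and the list had camera adjusted p = 1.45e-06 and adjusted p = 0.57 with an estimated correlation. Of the IFNγ-inducible GTPases and regulators 11 of 19 fell, such as Gbp4 (-2.66 ± 0.17) and the cytokine signalling suppressor Socs1 (-2.33 ± 0.11), and 3 rose, none of them with spike-in scaling, where 17 fell. The list did not pass (camera adjusted p = 0.0778), though it did without LPS_IFNg_emodin replicate 1 (0.0353) and with quantile scaling (0.00777), spike-in scaling (0.0444) and normexp (0.0158). The NF-kB targets went both ways, with 7 up, 10 down and 8 not called of 25 (camera adjusted p = 0.74), and Ccl2 among those that fell (-3.31 ± 0.32). With spike-in scaling 1 of them rose and 19 fell. MHC class I and class II presentation did not pass, with 5 up and 8 down of 16 (camera adjusted p = 0.42, and 0.0251 with quantile scaling) and 1 up and 5 down of 11 (0.324), and with spike-in scaling no gene of either rose, with 14 and 11 down.

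Metabolic and stress lists also moved. Cholesterol synthesis fell further, with 17 of 23 genes down and 4 up, Idi1 at -2.15 ± 0.09 and Hsd17b7 at least 5.01-fold lower, at camera adjusted p = 0.00387 and adjusted p = 0.57 with an estimated correlation. Of 21 NRF2 targets 15 fell and 3 rose, at camera adjusted p = 0.00506 and adjusted p = 0.57 with an estimated correlation. The malic enzyme Me1 changed by -3.85 ± 0.18 and the quinone reductase Nqo1 by -2.87 ± 0.15, whereas Hmox1, the haem oxygenase, rose by 1.18 ± 0.11. Of 22 cell cycle genes 12 fell and 4 rose, including the kinases Aurka (-2.69 ± 0.14) and Cdk1 (-2.68 ± 0.16), with camera adjusted p = 0.0345 and adjusted p = 0.57 with an estimated correlation. That call ended with normexp (0.0887), spike-in scaling (0.0875) and the filter to probes detected on all arrays (0.135). The median change of the cell cycle list was -1.06, and -0.27 with bounds in place of undetected levels. The xenobiotic enzyme Cyp1b1 changed by -6.96 ± 0.35, and the aryl hydrocarbon receptor list, with 5 of 8 down and 2 up, did not pass (camera adjusted p = 0.137). Cyp1b1 lay close to background on emodin replicates 2 and 3, at -4.64 and -4.53. With spike-in scaling 1 gene each of the cholesterol, NRF2 and aryl hydrocarbon receptor lists and 2 of the cell cycle list rose.

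Other lists were higher with emodin, by amounts that depended on the scaling. Of 14 p53 targets 13 rose and 1 fell, with Gdf15 at 3.06 ± 0.13, the apoptosis gene Bbc3 at 1.76 ± 0.10, camera adjusted p = 0.000734 and adjusted p = 0.347 with an estimated correlation. The list mean was 0.98, and 0.25 with spike-in scaling, where 4 rose and 3 fell. Of 24 lysosome genes 22 rose, among them the regulator Tfeb (1.81 ± 0.07) and the protease Ctsl (1.15 ± 0.09), at camera adjusted p = 8.08e-06 and adjusted p = 0.342 with an estimated correlation, but the list mean of 0.65 turned to -0.08 with spike-in scaling, where 2 rose and 5 fell. All 24 ribosomal protein genes rose, with Rpl3 at 1.31 ± 0.14, camera adjusted p = 1.45e-06 and adjusted p = 0.57 with an estimated correlation, and their mean of 0.79 became 0.06 with spike-in scaling, where 2 rose and none fell, and 0.35 with quantile scaling. Of 9 H3K27 methylation enzymes, which set or remove a repressive histone mark, 7 rose and 1 fell, and 8 rose when adjusted over the list alone, led by Ezh2 (1.47 ± 0.10), at camera adjusted p = 0.0329 and adjusted p = 0.342 with an estimated correlation. Their mean of 0.67 turned to -0.06 with spike-in scaling, where 1 rose and 1 fell, and the call ended with normexp (0.0615). In the other lists of this comparison named above, counts adjusted over the list alone were equal to those given.

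Mrc1, which LPS plus IFNγ had lowered, rose by 3.25 ± 0.28 with emodin, and Clec10a by 0.92 ± 0.21, a call that ended with spike-in scaling (0.19, adjusted p = 0.314). The alternative activation list as a whole had 5 genes up and 5 down of 15 (camera adjusted p = 0.852), a mean of 0.44 (-0.29 with spike-in scaling, where 3 rose and 8 fell) and a median of -0.10, with the chemokine Ccl22 at least 6.54-fold higher. Arg1, arginase, changed by -1.61 ± 0.60 (adjusted p = 0.0298), a call that ended without LPS_IFNg replicate 1 (0.0618) or 3 (0.0851) or LPS_IFNg_emodin replicate 2 (0.0888) or 3 (0.082). Chil3 had a log2 difference of 1.23 ± 0.58 (adjusted p = 0.0756), and passed with the replicate numbers as a block on the 8 arrays (6.04e-05), and without control replicate 1 (0.0236) or 4 (0.00979). Among single genes, Hamp, the iron hormone hepcidin, was at least 233-fold higher. Pgm5 rose by 6.05 ± 0.14 with the probe used and by less with its other probes. Its probes also differed in the direction of change in LPS_IFNg against control. Serpinb2 was at least 539-fold, Cxcl5 at least 80.9-fold and Sprr2e at least 32-fold lower, and Ly6a fell by -6.85 ± 0.38. Of 11 markers of mesothelial cells and fibroblasts 6 fell in the same comparison and none rose (camera adjusted p = 0.0778). The list mean was -1.91, and the median -0.98 with bounds in place of undetected levels. On the 4 emodin arrays, where that list had the values given above, Ly6a lay at -0.06, -1.70, -1.36 and -0.56. Gapdh, often used as a reference gene, had a log2 difference of 0.25 ± 0.11 with the probe used (adjusted p = 0.0561) and of -0.17 to -0.55 with its 6 other probes, and it turned to -0.21 and -0.47 with quantile and spike-in scaling. It passed upwards without LPS_IFNg_emodin replicate 4 (0.0235), LPS_IFNg replicate 1 (0.0462) or control replicate 2 (0.0196).

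**Figure D3:**
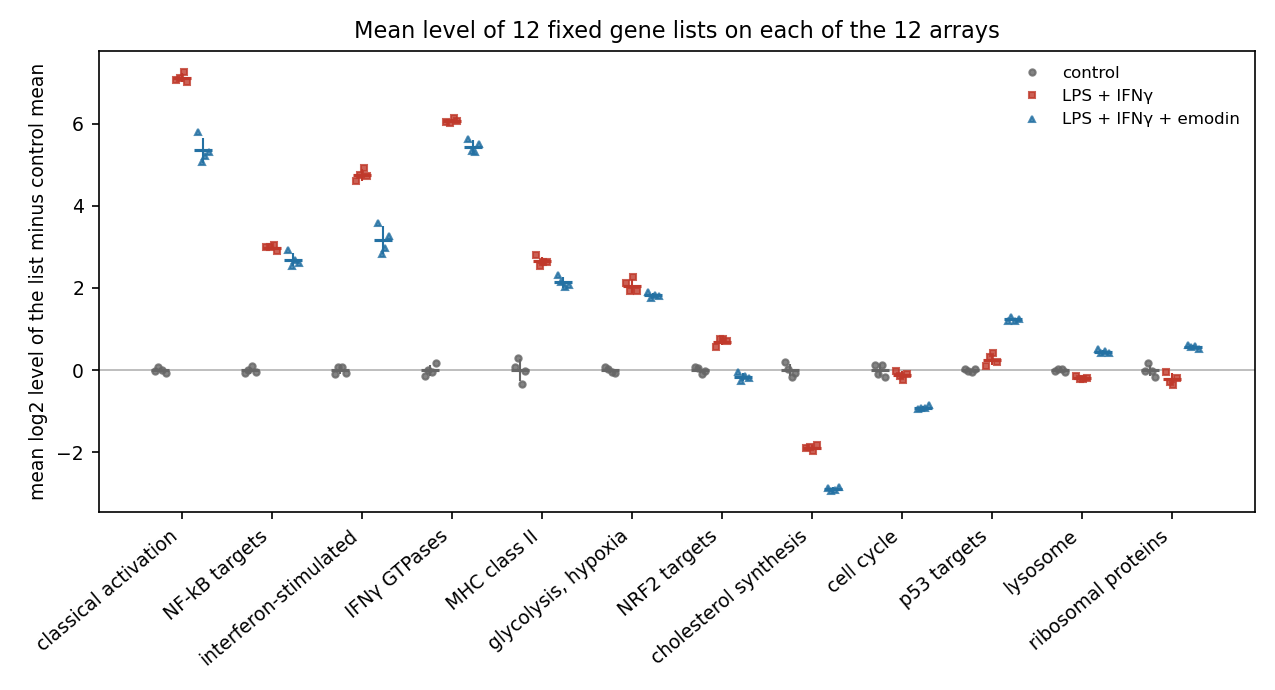
Mean log2 level of 12 gene lists on each array minus the mean of the control arrays, with 1 point per array, and the mean and SD of the 4 arrays of each group as lines. The mean of the interferon-stimulated list lay 4.75 above control in LPS_IFNg and 3.16 above it in LPS_IFNg_emodin, and that of cholesterol synthesis changed by -1.88 and -2.90.

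Emodin opposed the change made by LPS plus IFNγ for many genes and added to it for others. Both contrasts called 3839 genes in opposite directions, 1896 up and then down and 1943 down and then up, where independent calls would give 1613 and 1658. The same direction was called for 2939 genes. Splits of the LPS_IFNg arrays into 2 and 2 gave 2970.2 opposed genes and 2256 in the same direction on average. Simulations without an emodin effect gave 0 of both, and so do not test whether opposed changes outnumber the others. The log2 changes of the 2 contrasts had a correlation across genes, which are not independent replicates, of -0.287 and a covariance of -0.467, against -0.0648 and -0.0159 simulated. Of the 1879 genes raised at least 2-fold by LPS plus IFNγ, 1052 fell with emodin (56%), such as Cst7, Ifi44 and Gbp4, and 383 rose further (20.4%), such as Ubd by 2.37 ± 0.26. Of the 1586 lowered at least 2-fold, 646 rose (40.7%), such as Bex1 by 4.80 ± 0.35, and 487 fell further (30.7%), such as Arhgap15, at least 2.44-fold. The mean share of the change removed was 0.262, with a range of 0.221 to 0.296 over 6 splits, at 0.347 for raised and 0.0561 for lowered genes. For lowered genes it ranged from -0.0053 to 0.106 over the splits, so its sign was not fixed. With spike-in scaling of the emodin contrast, 3305 genes were up and then down but only 523 down and then up, and 2758 were down in both. Of the genes lowered at least 2-fold, 277 then rose (17.5%) and 849 fell further (53.5%), and of those raised, 1510 fell (80.4%) and 138 rose further (7.34%). The share removed was then 0.551 for raised and -0.26 for lowered genes, so the reversal of lowered genes turned with the scaling.

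The cells with LPS, IFNγ and emodin still differed from control in the direction of activation. Nos2 remained 10.06 ± 0.17 higher on the log2 scale (adjusted p = 8.75e-13), Cxcl9 at least 10070-fold, Ubd at least 1406-fold and Ccl12 at least 688-fold. Il1b stood 4.82 ± 0.43 and Cd86 1.18 ± 0.22 above control, and Mrc1, at 0.32 ± 0.28, did not pass (adjusted p = 0.304). Of 13169 genes 10268 were called, 5239 up and 5029 down, and 72.54% did not overlap, where chance gives 2.86%. The percentile over detected probes and no filter on dim probes gave 4329 up and 5999 down, and 8407 up and 5221 down.

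Of 20 classical activation markers 18 rose and 2 fell against control, with camera adjusted p = 5.83e-07 and adjusted p = 0.174 with an estimated correlation. All 27 interferon-stimulated genes rose, with camera adjusted p = 1.89e-09 and adjusted p = 0.242 with an estimated correlation. Cholesterol synthesis had 21 of 23 genes down and none up, with 1 up when adjusted over the list alone, at camera adjusted p = 1.45e-08 and adjusted p = 0.155 with an estimated correlation. Idi1 changed by -5.02 ± 0.09. The p53 targets had 11 of 14 up and 2 down, with Cdkn1a at 2.88 ± 0.11, camera adjusted p = 0.00835 and adjusted p = 0.242 with an estimated correlation. Lysosome genes (19 of 24 up, mean 0.45, camera adjusted p = 0.0107, adjusted p = 0.253 with an estimated correlation) and ribosomal protein genes (23 of 24 up, mean 0.57, camera adjusted p = 0.000511, adjusted p = 0.509 with an estimated correlation) turned to means of -0.07 and -0.08 with quantile scaling, and both calls ended. The scalings named above moved the median of all genes to between -0.14 and -0.18 in this comparison.

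Markers of other cell types were measured in each group. The neutrophil list did not pass in the 3 comparisons (camera adjusted p = 0.758, 0.941 and 0.594). Of its 11 genes 4 rose and 5 fell with LPS plus IFNγ, 6 rose and 5 fell with emodin, and 2 rose and 4 fell against control. Its mean level was -0.83, -1.13 and -1.44 in control, LPS_IFNg and LPS_IFNg_emodin, and that of the macrophage list 2.76, 2.15 and 1.63. The neutrophil gene S100a8, named after its values were seen, lay at 3.15, 3.76 and 2.91 in these groups. S100a9 of the same list lay at -4.16 to -3.17, -6.58 to -4.50 and -4.52 to -2.06 on their arrays. Of 14 macrophage genes 4 rose and 9 fell with LPS plus IFNγ (camera adjusted p = 0.144), with Vsig4 at -2.85 ± 0.27. With emodin 5 rose and 7 fell (0.618), and against control 2 rose and 9 fell (0.0364; adjusted p = 0.286 with an estimated correlation), a call that ended with the percentile over detected probes (0.0675). Mesothelial and fibroblast genes fell in 6 of 11 with emodin and rose in none, such as Wt1 (-4.81 ± 0.78) and Col1a1 (-3.71 ± 0.38). Wt1 lay close to background on emodin replicates 2 and 3, at -5.96 and -6.13, so its change is not fully measured. The median change of the list was -1.55, and -0.98 with bounds in place of undetected levels. That list had camera adjusted p = 0.0778, and passed with the replicate block on 8 arrays (0.00818), without LPS_IFNg replicate 2 (0.0403) and without LPS_IFNg_emodin replicate 1 (0.0305). Against control 10 of its 11 genes fell (camera adjusted p = 0.0216; adjusted p = 0.593 with an estimated correlation), a call that ended with quantile scaling (0.0534). With emodin, 2 of 8 B cell genes rose and 4 fell (camera adjusted p = 0.618), 1 of 6 T and NK cell genes rose and 3 fell (0.618), 1 of 5 mast cell genes rose and 1 fell (0.965), and 2 of 7 dendritic cell genes rose and 4 fell (0.618). Those 4 lists did not pass in the comparisons with control either. The 3 eosinophil genes and the 1 erythroid gene were too few for the test, with 2 eosinophil genes up and the erythroid gene not called with emodin. With spike-in scaling no macrophage, T and NK cell, dendritic cell or eosinophil gene rose, and 1 B cell, 1 mast cell and 4 neutrophil genes did.

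Xist, expressed from the inactive X chromosome, lay between -0.27 and 1.08 on 10 arrays and at -6.22 and -6.27 on replicate 3 of LPS_IFNg and of LPS_IFNg_emodin. On those 2 arrays the Y-linked Ddx3y lay at -0.01 and -1, and it was not well above background on the other 10. All treated samples are labelled female, and 2 of the controls, which had Xist signal, are labelled male, so the Xist state went against the labelled sex on 4 of 12 arrays. Slide and group cannot be told apart in the comparisons with control. Of 28 gene lists, 13 were called in LPS_IFNg against control, 9 in LPS_IFNg_emodin against LPS_IFNg and 17 in LPS_IFNg_emodin against control. For these numbers, other splits of the arrays gave as many as the real groups in each comparison, so chance was not excluded for them. Most of those splits kept most arrays of each real group together, and so still carried part of the treatment difference. The splits therefore cannot decide whether chance gives such numbers.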

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

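The tests of the signal against the spike-ins, of the sex-linked probes and of the ribosomal protein genes were chosen only after the results were seen. In 22 of 371 groups of 4 values of named genes and array measures, 1 array lay apart by more than Dixon's critical value for its gap to the nearest other array as a share of the group's range, and chance gives about 1 in 20.

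Among control arrays this share of the range was 0.975 for Chac1 (replicate 3, lowest), 0.94 for Socs1 (replicate 2, highest), 0.909 for Hamp (replicate 4, lowest), 0.897 for Ahrr (replicate 4, highest), 0.871 for Ccl12 (replicate 3, highest), 0.861 for Bbc3 (replicate 1, lowest) and 0.84 for Hspa1a (replicate 2, lowest). Among LPS_IFNg arrays it was 0.946 for Ddit3 (replicate 4, highest), 0.91 for S100a9 (replicate 1, highest), 0.855 for Hcar2 (replicate 1, highest), 0.837 for Dhcr7 (replicate 3, lowest) and 0.833 for Cd28 (replicate 2, lowest). Among LPS_IFNg_emodin arrays it was 0.922 for Ltf (replicate 4, highest), 0.91 for Smpd3 (replicate 4, highest), 0.897 for Vnn1 (replicate 1, lowest), 0.894 for Chac1 (replicate 1, lowest), 0.888 for Cdkn1a (replicate 4, lowest) and 0.847 for Cdo1 (replicate 2, lowest). Of 10212 probes without a gene symbol, which entered no comparison, 167 were well above background in LPS_IFNg, on no control array, and at least 2-fold higher. In LPS_IFNg_emodin against LPS_IFNg, 1777 of these probes were called at least 2-fold higher, 347 of them from below background on every LPS_IFNg array, and 687 lower, where named genes gave 1364 and 2135.

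Replicate 3 of both treated groups lacked Xist, with shares of the range of 0.975 in LPS_IFNg and 0.903 in LPS_IFNg_emodin, and carried Ddx3y, with shares of 0.988 and 0.879. Failed spots of one probe are excluded, since both Xist probes were well above background on 10 arrays and not on these. In all, 4 of 4 sex-linked probes with signal set these arrays apart. Those of Ddx3y and Eif2s3y had signal only there, so their part in that count was fixed by the choice of probes. The probes of Uty and Kdm5d were not well above background on any array. A swap with control arrays is excluded, since at least 99.22% of 767 genes lay nearer the treated mean on each of these arrays. RNA pooled from both sexes would carry Xist, and 0 of 4 Xist spots on these arrays were above background. That count restates the absence of Xist by which these arrays were picked, so it is no separate test. Sex labels that do not follow the animals may account for the pattern, as 2 of 2 controls labelled male had Xist and no Y-linked signal. No biological explanation was tested.

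Gene signal was lower against the spike-ins in LPS_IFNg_emodin than in LPS_IFNg. A loss over the whole array in hybridization, washing or scanning is excluded, since the spike-ins moved by -0.0501 ± 0.0595 (SE, n = 4 per group) and the median gene by -0.892 ± 0.101. Background subtraction of dim probes is excluded as the whole cause, since the 1317 brightest genes, with a median signal at least 1010 times the local background, shifted by -0.588 ± 0.087. Poorer labelling of whole reactions would lower the spike-ins too, and their change of -0.0501 ± 0.0595 argues against it. More spike-in mix, poorer labelling of the sample RNA alone and less messenger RNA in these cells cannot be told apart. Each would give the shift of -0.842 ± 0.112 (exact two-sided permutation p = 0.0286 over free assignments and 0.125 within the 4 pairs, each the smallest possible).

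Ribosomal protein genes were higher in LPS_IFNg_emodin than in LPS_IFNg, by 0.786 on the log2 scale, and by 0.0614 with spike-in scaling, so scaling each array to its own genes could account for the absolute rise. A trend with brightness is excluded as the whole cause, since 99.99% of 10000 random lists of equal brightness had a lower mean, with a median of 0.354. The excess of 0.435 ± 0.0517 over such genes (SE, n = 4 per group, exact two-sided permutation p = 0.0286 over free assignments and 0.125 within the 4 pairs, each the smallest possible) is in line with more ribosomal protein messenger relative to other bright messengers, as a hypothesis.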

How the results depend on the processing

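Spike-in scaling, the block on 8 arrays and leaving out replicate 3 of both treated groups were chosen after the data were seen. The counts of genes called stayed within 1.5 times their values except with a 2-fold minimum, which by construction keeps fewer genes (3465, 3499 and 5069 for LPS_IFNg against control, LPS_IFNg_emodin against LPS_IFNg and LPS_IFNg_emodin against control). Leaving out each array gave 8623 to 9116, 9082 to 9658 and 9963 to 10335 genes, 3543 to 3837 opposed genes, a share removed of 0.245 to 0.275, and 12 to 14, 9 to 11 and 17 to 17 lists. The share removed was 0.214 with probes above background on all 12 arrays, where fewer genes are tested, and 0.315 with spike-in scaling. Camera with an estimated correlation called 0, 0 and 0 lists, and fry, which does not compare a list with other genes, called 21 and 21 in the first 2 comparisons. Over all alternatives, 26 values of named genes reversed, 104 lost and 61 gained a call and 8816 did neither, and for lists these numbers were 8, 64, 55 and 2185. The cause of the reversals below was not tested. Against LPS_IFNg, spike-in scaling turned the lysosome list to -0.0772, the H3K27 list to -0.0566, and the log2 changes of Mamdc2 to -0.11, Irf1 to -0.10, Gapdh to -0.47, Gbp5 to -0.61, Tap1 to -0.30, Cdkn1a to -0.34, Hk2 to -0.25, Hcar2 to -0.26 and Calhm6 to -0.27. Before spike-in scaling, Irf1 and Cdkn1a rose by 0.63 and 0.38 with the probes used and by 1.65 and 1.12 with their other probes. Their turns are therefore given for the probes used only. Normexp turned Rgs18 to 0.73, Fasn to 0.0042, Rasgrp3 to 0.0143 and S1pr1 to 0.0618. Gapdh turned to -0.21 with quantile scaling and the value table and to -0.32 with the mean of its probes, and Gbp5 to -0.28 with the value table. Against control, quantile scaling and the value table turned oxidative phosphorylation to -0.392 and -0.401, the lysosome list to -0.0708 and -0.0778, the ribosomal list to -0.0841 and -0.0927, Rpl3 to -0.20 and -0.21, Rpl10a to -0.38 and -0.39, and Ctsd to -0.15 and -0.15. Mmp9 turned to 0.0197 with normexp, Tfeb to -0.0207 with the percentile over detected probes, and Xist to 0.825 without replicate 3 of the treated groups. Signal over background limits genes not detected in 1 group to bounds.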

Other observations

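The test that compares interferon-stimulated with NF-kB target genes was chosen only after the result was seen, and the counts over other splits were planned. Genes of the unfolded protein and integrated stress response moved apart with emodin. Of 20 tested, 5 rose and 11 fell, with 6 up when adjusted over the list alone (camera adjusted p = 0.42). Psat1, of serine synthesis, fell by 2.96 ± 0.18 on the log2 scale and Chac1 by 1.15 ± 0.19, while the transcription factor Ddit3 rose by 1.22 ± 0.12. With LPS plus IFNγ 13 of the 20 had risen and 1 fallen, with 14 up when adjusted over the list alone (camera adjusted p = 0.00192, and adjusted p = 0.252 with an estimated correlation).

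Among 24 components of TLR4 and IFNγ receptor signalling 6 rose and 9 fell with emodin (camera adjusted p = 0.767), with a mean of -0.14 and a median of 0.08. Tlr4, the LPS receptor, fell by 2.22 ± 0.15. Of 27 oxidative phosphorylation genes 6 rose and 12 fell, with 11 down when adjusted over the list alone (camera adjusted p = 0.618, and 0.0314 with quantile scaling). Of 13 LXR targets 4 rose and 7 fell (0.726), with Abca1 at -1.41 ± 0.18. Of 11 heat shock genes 2 rose and 6 fell (0.618), and of 21 genes of glycolysis and hypoxia 4 rose and 11 fell (0.199, and 0.00633 with quantile scaling). With spike-in scaling 2 genes of the stress response, 1 of TLR4 and IFNγ signalling and 3 LXR targets rose, and no gene of the other 3 lists.

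Interferon-stimulated genes may lose a larger share of their rise with emodin than NF-kB targets do, by an amount that depended on the scaling. The 27 interferon-stimulated genes lost 33.4% of their mean log2 rise and the 25 NF-kB targets 9.86%, a ratio of 3.39, with 0 genes in both lists. With spike-in scaling of the fall these shares were 48.6% and 34.2%, a ratio of 1.42. The first share was larger in 4 of 4 pairs with either scaling, by at least 18.5 and 9.51 percentage points. The change of the first list lay -1.29 ± 0.126 from that of the second (SE, n = 4 per group), a difference that spike-in scaling, 1 factor per array, does not move. The exact two-sided permutation p of this difference was 0.0286 over free assignments and 0.125 within the 4 pairs, each the smallest possible. It does not test the shares. The first list had risen by 4.75 and the second by 2.98, so an equal share removed would also give the first a larger fall. The lists were fixed before the data were examined, and this comparison of them was not.

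Over free splits, chance was excluded for the numbers of genes called. Of 35 splits of the 8 arrays, 1, the real one, gave as many in each comparison. It gave 9065, 9483 and 10191 genes on those 8 arrays, with 0 as the highest other. For LPS_IFNg_emodin against LPS_IFNg, where arrays share replicate numbers, the 8 splits that part every pair are too few for a share under 5%. The real one gave 9483 genes and the highest other 0, so chance was not excluded within pairs. Chance was not excluded for the numbers of lists called, and the splits cannot decide it. Most splits that reached the real number kept most arrays of each real group together, and so still carried part of the treatment difference. For LPS_IFNg against control, 11 of 35 splits gave as many as the real 12 (highest other 15). For LPS_IFNg_emodin against LPS_IFNg, 11 of 35 gave as many as the real 9 (highest other 15). Of the 8 splits that part every pair, 4 did so there (highest other 10). For LPS_IFNg_emodin against control, 5 of 35 gave as many as the real 17 (highest other 19). For the share removed of 0.262, 2 of 70 assignments of the treated arrays gave as much, the real one and its mirror with both treated groups exchanged (0.378), and the highest of the rest was 0.105. Mixed groups shrink the difference between the treated groups, and the share with it. The share over assignments therefore shows that the 2 treated groups differ and does not test reversal. The assignments that part every pair are too few for a share under 5%. For the 3839 opposed genes the same 2 of 70 gave as many (6567 in the mirror) and every other gave at most 1, because mixed groups call almost no gene with emodin, so this count repeats that of genes called and does not test opposition.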
